A study of Mus musculus with 16 samples.

How the data were processed

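RNA from whole inguinal mammary glands of mice was sequenced in 16 libraries. Mid-lactation is from the title. The age label is postnatal day 16, and the labels do not say if this is the age of the animals or the days since they gave birth. The labels give 4 groups of 4 libraries, which cross diet (NCD, or HFD, a high fat diet given in lactation) with treatment (control or metformin, a drug that lowers blood glucose). The labels do not expand NCD, or the PN in the descriptions. Total RNA was extracted with the Qiagen RNeasy Mini Kit and libraries were made with the NEBNext Ultra II Directional kit, per the labels' protocols. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Replicates were numbered in accession order, and no label pairs libraries across groups.

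The deposited files hold an estimated count and a TPM value for each transcript and library, per the file headers, which are those of Salmon. TPM as the authors deposited it is relative to the effective coding length and sums to the same total in each library. Salmon 1.3.0, DESeq2 1.28.1 and the build GRCm38.p6 are named, with no order or role, per the submitters' processing notes. The options for strand, for sequence bias and for duplicate sequences, and any filter, are not given in the sources used here. The files list 58204 transcripts. For 56929 of the 56929 transcripts with the same version in GENCODE M21 (Ensembl 96) and a coding sequence there, the listed length was within 3 bases of the coding length. Reads from untranslated regions and noncoding genes are therefore not measured. Genes of near-identical coding sequence (immunoglobulin, glutathione transferase and Ly6 families, and mitochondrial genes with nuclear copies) can share reads and are uncertain. Strand options being unknown, overlapping antisense genes cannot be told apart.

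Estimated counts of 57452 transcripts were summed to 22196 genes of GENCODE M21 and rounded to whole numbers. The other 752 transcripts, with 0.165 to 0.218% of the counts of a library, had no match and were left out. Gene coordinates are those of that annotation on GRCm38. Totals over genes ranged from 8649316 to 39156617 counts per library, with a median of 28944266. A floor of 3 counts corresponds to 0.077 to 0.347 CPM. Counting intervals are exact at the 95% level. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries looked like a single library deposited again, with a lowest chi-square per degree of freedom of 13.41 over 120 pairs.

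Genes were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test, in a single fit with 4 group means over all 16 libraries, after filterByExpr by group and TMM scaling. This left 12506 genes, 12 residual degrees of freedom, 4.38 prior degrees of freedom and a common biological coefficient of variation of 0.233. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. All tests were two-sided. The 7 contrasts were the diet effect without and with metformin, the metformin effect on NCD and on HFD, their interaction, and both effects averaged over the other factor. Group levels are CPM after TMM scaling. Standard errors (SE) belong to log2 fold changes. The count of libraries showing a direction compares each library with the mean of the other group, pooled over the other factor in averaged contrasts. With 4 libraries against 4, chance leaves the groups of a gene without overlap in 2.86% of cases.

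Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a contrast, and a list with an adjusted p under 0.05 is called shifted. Other splits of the libraries shifted up to 20 lists, so a shift alone does not exclude chance. Camera with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance one way, were alternatives. Of 45 lists, 42 had at least 5 tested members. T cell, keratinocyte and skin, and neutrophil markers had too few. A list score is the mean log2 CPM, at a prior count of 2, of its tested members in a library.

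The groups, contrasts, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes, for each contrast, up to 12 genes with the largest and up to 12 with the lowest log2 fold change among called genes with a mean of at least 1 CPM and a symbol that is not a clone name, and where fewer than 5 are called, those and then the lowest p-values up to 6 genes. It adds up to 4 tested members of each described list with the lowest p-values, and, in every contrast, 13 genes (Csn2, Wap, Lalba, Fasn, Acaca, Acly, Scd1, Xdh, Lpl, Adipoq, Lep, Krt18 and Acta2). For lists the text gives examples among these members. Some genes that the rule names are not reported here, but stay in the counts. Cdkn1a, Ccng1 and Eda2r were added for metformin on NCD after their values were seen. The alternatives fixed then were DESeq2 size factors, library size only, TMM without milk protein genes, no filter, at least 1 CPM in 8 libraries, counts rebuilt from TPM, a term for title numbers up to 10 against those from 14 (a gap that may mark batches), only the 2 groups compared, limma-voom, DESeq2 1.42.0, and leaving out each library in turn. Chosen after seeing the data were a correction for the trend with coding length and GC content (loess, span 0.5), 3 exclusions of a pair of libraries, and the lists of p53 and aryl hydrocarbon receptor targets.

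The tests were tried on simulated counts with 200 changed genes. At folds of 1.5, 2 and 4 the edgeR test recovered 19.4, 59.7 and 96.9% of them for the diet effect without metformin (12404 genes, 4.7% of calls false), and 28.8, 58.2 and 90.8% for the metformin effect on NCD (12404 genes, 4.7% false). Recovery was 16.7, 53.7 and 87.7% for the metformin effect on HFD (12420 genes, 0% false), and 19.4, 64.2 and 86.2% for the diet effect with metformin (12407 genes, 4.1% false). For the interaction it was 1.5, 30.8 and 69.7% (12419 genes, 1.5% false).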

Results

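Gene expression was measured by RNA sequencing in whole inguinal mammary glands of mice, in mid-lactation by the title and at postnatal day 16 by the age label. The study asked how a high fat diet given in lactation (HFD) and metformin, a glucose-lowering drug, affect gene expression in the gland. Diet (NCD or HFD) was crossed with treatment (control or metformin), with 4 libraries in each of 4 groups. Totals over genes were 30070448 ± 1383868 counts for NCD control, 30536811 ± 6026583 for NCD metformin, 26332393 ± 13178408 for HFD control and 25379040 ± 7567766 for HFD metformin (SD, n = 4). Libraries are named by group and number. The shallowest were HFD control 4 with 8649316 counts and HFD metformin 1 with 14508606.

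Transcripts of milk proteins, the caseins and whey proteins secreted by the lactating epithelium, took most of the counts. Their share was 71.49 ± 1.21% in NCD control, 71.03 ± 0.23% in NCD metformin, 74.21 ± 0.98% in HFD control and 74.0 ± 1.94% in HFD metformin (SD, n = 4). Transcripts of the mitochondrial genome took 2.39 ± 0.23% in NCD control, 3.52 ± 0.19% in NCD metformin, 2.18 ± 0.18% in HFD control and 2.8 ± 0.19% in HFD metformin (SD, n = 4). Single libraries had high scores for markers of other tissue. The skeletal muscle score was 6.92 log2 CPM in NCD control 3, which also had the highest adipocyte score, 4.54. HFD metformin 4 had a cell cycle score of 2.03, against -0.60, 0.01 and 0.23 in the other libraries of its group.

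**Figure D1:**
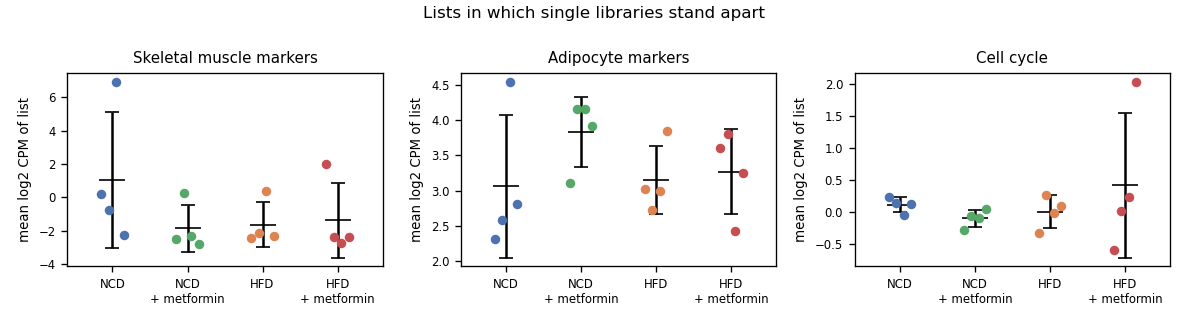
Scores of 3 gene lists (skeletal muscle markers, adipocyte markers, cell cycle) in each library, as the mean log2 CPM of the list on the y axis, by group on the x axis. Points are libraries, horizontal marks and error bars the mean and SD of 4 libraries; NCD control 3 lies at 6.92 for muscle and HFD metformin 4 at 2.03 for cell cycle.

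Without metformin, glands on HFD had far less Cyp1a1, a cytochrome P450 that oxidises foreign compounds and is induced through the aryl hydrocarbon receptor. Its level was 1.83 ± 0.67 CPM on NCD and 0.0285 ± 0.0412 CPM on HFD (SD, n = 4), or 3 counts over the HFD libraries against 242, a ratio of 1.6% (95% exact counting interval 0.329 to 4.74%). Prol1, which encodes a secreted proline-rich protein, fell from 135 ± 70.2 to 3.92 ± 2.1 CPM (SD, n = 4). Also lower were Adig, a gene of adipocyte differentiation (log2 fold change -1.25), the cell adhesion gene Mpzl2 (-1.10) and Renbp, a sialic acid pathway epimerase (-1.08). Ddah1, which degrades methylated arginines, rose by 2.04 ± 0.35 (SE) on the log2 scale, and Scnn1b, a subunit of the epithelial sodium channel, by 0.66 ± 0.11.

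These were among the 8 of 12506 genes called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 lower and 2 higher, with 881 genes at an unadjusted p under 0.05 against 625 by chance. Adjusted p was 0.0012 for Cyp1a1 (log2 fold change -5.74 ± 0.67 SE) and 0.00713 for Prol1 (-5.04 ± 0.70), and all 4 HFD libraries lay beyond the NCD mean for each of the 8. It was 0.012 for Adig, 0.0411 for Mpzl2 and Ddah1, and 0.0348 for Renbp and Scnn1b (edgeR). On GRCm38, Cyp1a1 (ENSMUSG00000032315.6) lies on chromosome 9 from 57687928 to 57703824 and Prol1 (ENSMUSG00000064156.8) on chromosome 5 from 88317312 to 88328814. Of the 8 calls 2 ended under no alternative, Cyp1a1 among them, and that of Prol1 ended without HFD control 3 (adjusted p = 0.0543, edgeR quasi-likelihood). Calls were lost in 18 of 30 alternatives for Mpzl2, 17 for Ddah1, 14 for Renbp (-0.36 in counts rebuilt from TPM), 12 for Scnn1b and 3 for Adig. The gap in title numbers, which may mark batches, partly followed diet. Of the controls only NCD control 1, 2 and 3 and HFD control 1 lay below it. With a term for this gap 5 genes were called, 0 higher and 4 of them among the 8. Adjusted p was 0.0789 for Mpzl2, Renbp, Ddah1 and Scnn1b (edgeR). Without 1 library the count was 4 (NCD control 1, NCD control 2 or NCD metformin 1), 5 (NCD control 3 or NCD metformin 2), 3 (HFD control 1), 2 (HFD control 3) or 13 (NCD metformin 3). Scaled by library size only, 39 genes passed, 2 higher and 37 lower, and the median of all genes moved to -0.16 on the log2 scale.

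Antioxidant and NRF2 target genes were lower on HFD without metformin as a list, with 15 of 17 members negative and a median log2 fold change of -0.25. No member passed over all genes and 6 were lower adjusted over the list alone (camera adjusted p = 1e-06, and adjusted p = 0.0213 with an estimated correlation). Gclm, a subunit of glutamate-cysteine ligase, had -0.49 ± 0.09 (SE, adjusted p = 0.0782), and the glutathione transferases Gsta4, Gsta3 and Gstm1, a family that can share reads, had -0.95, -1.46 and -0.70. The integrated stress response list was higher, with a median of 0.43 and 0 of 24 members called (3 adjusted over the list alone, camera adjusted p = 1e-06, adjusted p = 0.565 with an estimated correlation). Its member Mthfd2, an enzyme of mitochondrial one-carbon metabolism, had 1.32, not called. Milk proteins (median 0.19, 0 of 17 called, 3 higher and 1 lower adjusted over the list alone) and milk fat globule and secretion genes (0.16, 0 of 13 called, 2 adjusted over the list alone) were also higher. Camera adjusted p was 0.00049 and 0.000507, with adjusted p = 0.498 with an estimated correlation for both. With library size only the medians of shifted lists moved by -0.2 to -0.15, as that of all genes did (-0.17), to 0.03 for milk proteins, -0.01 for milk fat globule genes, 0.25 for the integrated stress response, 0.09 for collagens and -0.42 for antioxidant genes. Collagens and extracellular matrix genes were higher (median 0.24, 0 of 25 called, 1 adjusted over the list alone, camera adjusted p = 0.000326, adjusted p = 0.729 with an estimated correlation), and Fn1, fibronectin, had 1.21 ± 0.24 (SE, adjusted p = 0.0863, and 0.0428 without NCD metformin 3).

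The sixth shifted list, skeletal muscle markers, had a median of -6.47, with 0 of 16 members called and 16 lower adjusted over the list alone (camera adjusted p = 1e-06, adjusted p = 0.729 with an estimated correlation). NCD control 3 had a muscle score of 6.92 log2 CPM, against 0.39 in the highest HFD control library. Of 42 lists, 6 were shifted, and the count was 12 without NCD control 1, 13 without NCD control 4, 10 without HFD control 1, 13 without HFD control 2 and 12 without NCD metformin 4. None of the genes named in every comparison passed, with log2 fold changes of 0.21 for Csn2, 0.30 for Wap, -0.01 for Lalba, 0.37 for Fasn, 0.49 for Acaca and 0.14 for Acly. Scd1 had -0.47, with 0.50 for Xdh, 0.24 for Lpl, -0.41 for Adipoq, 1.15 for Lep, 0.13 for Krt18 and 0.12 for Acta2, with a lowest adjusted p of 0.302 for Xdh. Without NCD control 3 Adipoq had 1.16, and the median of adipocyte markers was 0.7 (camera adjusted p = 0.0026), against -0.36, not shifted, with it.

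With metformin on NCD, 10 of 33 nuclear genes of respiratory complexes III to V, 6 of 24 of cholesterol synthesis and 3 of 7 of ketone body metabolism were called higher, and 5 of 21 immediate early genes lower. Prss53, a serine protease gene, rose from 3.0 ± 0.297 to 13.3 ± 0.712 CPM and Pycard, the adaptor of the inflammasome, to 15.2 ± 3.95 CPM (SD, n = 4). Ptgr1, an NADPH-dependent prostaglandin reductase, rose from 8.69 ± 1.11 to 21.2 ± 3.63 CPM (SD, n = 4). Cdkn1a, the cyclin-dependent kinase inhibitor p21, fell from 17.4 ± 5.42 to 2.51 ± 1.29 CPM, and Ccng1, cyclin G1, from 28.3 ± 2.74 to 12.7 ± 1.83 CPM (SD, n = 4). Eda2r, a receptor of the tumour necrosis factor receptor family, fell from 2.18 ± 0.283 to 0.407 ± 0.0725 CPM (SD, n = 4). Cdkn1a, Ccng1 and Eda2r were singled out after their values were seen.

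In all, 1255 of 12506 genes passed edgeR's quasi-likelihood test, 501 higher and 754 lower, with 3488 at an unadjusted p under 0.05 against 625 by chance. Adjusted p was 7.94e-05 for Prss53 (log2 fold change 2.15 ± 0.20 SE), 0.00554 for Pycard (1.46 ± 0.23), 0.00196 for Ptgr1, 0.00097 for Cdkn1a (-2.80 ± 0.35) and 0.000156 for Ccng1 (-1.15 ± 0.12). The groups of these genes did not overlap. Further large increases were those of Pcolce2 (1.72), Angptl2 (1.55), Kcnk5 (1.52), Rragd (1.34), Ly6a (1.3), Efhd1 (1.3) and Glrx (1.18), with Ighg2c at 2.62, where Ly6a and Ighg2c belong to families that can share reads. Prss53 (ENSMUSG00000044139.12) lies on chromosome 7 from 127885841 to 127890970 and Cdkn1a (ENSMUSG00000023067.14) on chromosome 17 from 29090976 to 29100727 (GRCm38). The calls of Prss53, Pycard and Ptgr1 ended under no alternative. Without NCD metformin 2 the value of Kcnk5 was 0.72, and its call was lost in 8 of 30 alternatives. Without 1 library the count was 384 (NCD control 1), 564 (NCD control 2), 788 (NCD control 3), 180 (NCD metformin 2) or 511 (NCD metformin 3). Under library size alone it was 990, 248 higher and 742 lower, with only the 2 groups compared 990, 482 higher and 508 lower, and in counts rebuilt from TPM 619, 315 higher and 304 lower.

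The 12 lowest fold changes were of Cyp24a1, the vitamin D 24-hydroxylase, and of skeletal muscle genes. Myh1 had -8.37 ± 1.75 (SE), Tnnc2 -7.87, Tnnt3 -7.29, Neb -7.29, Acta1 -7.18, Tcap -7.12, Ckm -6.96, Tnni2 -6.76, Ttn -6.74, Ryr1 -6.30 and Mylpf -5.47, all with adjusted p under 0.05 (edgeR quasi-likelihood) and with groups that overlapped. Acta1, the actin of skeletal muscle, was 105 ± 206 CPM in NCD control (SD, n = 4), with 414 CPM in NCD control 3 and 3.61, 1.3 and 0.239 CPM in the others. Of 16 muscle markers 12 were called lower, and 1 without that library. Ryr1 then had a log2 fold change of 0.05. Tcap had 8 counts with metformin against 1203, and against 60 without that library, a ratio of 10.4% (95% exact counting interval 4.28 to 21.8%). Cyp24a1 had 16 against 702, and against 257 without it, 4.84% (2.73 to 8.01%). Their fold changes were then -3.15 (adjusted p = 0.165) and -4.26 (adjusted p = 0.0693, edgeR), and these fitted values depend on the prior count. Cyp24a1 had -5.35 ± 1.42 (SE, adjusted p = 0.0297, edgeR) over all libraries, and lost its call in 11 of 30 alternatives. Without NCD control 3 the 6 lowest fold changes were those of Myh1 (-4.71), Cst6 (-4.55), Pip (-4.53), Gstp2 (-4.11), Adgrf3 (-3.86) and Gdf15 (-3.73).

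All 13 tested genes of the mitochondrial genome had positive fold changes with metformin on NCD, and 9 rose over all genes (10 adjusted over the list alone, median 0.49, camera adjusted p = 4.61e-10, adjusted p = 0.44 with an estimated correlation). Among them mt-Co1, a subunit of cytochrome c oxidase, rose from 6157 ± 534 to 10560 ± 563 CPM (SD, n = 4), though nuclear copies can share their reads. Of nuclear subunits, 10 of 33 in complexes III to V rose (21 adjusted over the list alone, median 0.39, camera adjusted p = 1.05e-10, adjusted p = 0.548 with an estimated correlation, as for the next 2 lists). In complex I 8 of 36 rose (20 adjusted over the list alone, median 0.37, camera adjusted p = 1.06e-08), with none lower. Cyc1 rose by 0.54, Cox8a by 0.53 and Ndufs7 by 0.43 on the log2 scale. Cox8a and Ndufs7 had 0.27 each, not called, with the length and GC trend removed. All 43 cytosolic ribosomal protein genes had positive values, of which 3 passed (3 adjusted over the list alone, median 0.25, camera adjusted p = 2.22e-08).

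Cholesterol synthesis genes were higher (median 0.44), with 6 of 24 called higher and 10 adjusted over the list alone (camera adjusted p = 7.57e-07, adjusted p = 0.548 with an estimated correlation). Msmo1 rose by 1.01, Lss, lanosterol synthase, by 0.99 and Sqle, squalene epoxidase, by 0.58 on the log2 scale. Of 24 genes of de novo fatty acid synthesis 5 rose (6 adjusted over the list alone, median 0.31, camera adjusted p = 4.44e-05, adjusted p = 0.499 with an estimated correlation). Among them were the citrate carrier Slc25a1 (0.74), Acly, ATP citrate lyase (0.62), and Elovl1 (0.53). Scores of adipocyte markers were 3.06 ± 1.01 log2 CPM in NCD control and 3.83 ± 0.5 in NCD metformin (SD, n = 4). Without NCD control 3, the highest control at 4.54, the median of these markers was 1.46, against 0.5 with it, and those of fatty acid and cholesterol synthesis were 0.36 and 0.44. Ketone body enzymes Bdh1 (0.72), Oxct1 (0.73) and Acat1 (0.71) rose, 3 of 7 members (3 higher and 1 lower adjusted over the list alone, median 0.69, camera adjusted p = 0.0382, adjusted p = 0.499 with an estimated correlation). Of 17 glycolysis genes 5 rose (5 adjusted over the list alone, median 0.17, and 0.11 with library size only, camera adjusted p = 0.0222, adjusted p = 0.548 with an estimated correlation), including Eno1 (0.61).

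Fatty acid oxidation genes and PPAR targets were lower, with 8 of 28 called lower and 1 higher (11 lower and 2 higher adjusted over the list alone, median -0.35, camera adjusted p = 0.0131, adjusted p = 0.548 with an estimated correlation). Ucp3, a mitochondrial carrier, fell by 1.40 and Cpt1a, carnitine palmitoyltransferase, by 1.01 on the log2 scale. Of 21 immediate early genes, which respond within minutes to stimulation, 5 fell (5 adjusted over the list alone, median -0.76, camera adjusted p = 1.48e-05, adjusted p = 0.548 with an estimated correlation), among them Dusp1 (-2.10), Ier3 (-1.47) and Fosl2 (-2.39). Involution and STAT3 genes were lower (8 of 27 called, 9 adjusted over the list alone, median -0.22, camera adjusted p = 0.000988, adjusted p = 0.499 with an estimated correlation), with Chil1 at -1.73 and Stat3 -0.79.

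Of markers of other cells 4 lists were shifted, each with adjusted p = 0.548 with an estimated correlation. Those of macrophages and monocytes were lower (2 of 15 called, 2 adjusted over the list alone, median -0.21, camera adjusted p = 0.0264), including Cd14 (-1.45). Endothelial markers were higher (1 of 16 called, 5 adjusted over the list alone, median 0.37, camera adjusted p = 0.0094). So were adipocyte markers (1 of 20 called, 1 adjusted over the list alone, median 0.50, camera adjusted p = 0.0084). Muscle markers were lower (12 of 16 called, 16 adjusted over the list alone, median -6.84, camera adjusted p = 0.000812). In all 15 of 42 lists were shifted, 10 higher and 5 lower. Of the genes named in every comparison only Acly passed (adjusted p = 0.0211, edgeR, higher in 4 of 4 libraries, its call lost in 4 of 30 alternatives). The others had log2 fold changes of 0.08 for Csn2, 0.11 for Wap, 0.31 for Lalba, 0.63 for Fasn, and 0.24 for Acaca. Scd1 had 0.50, with 0.13 for Xdh, -0.05 for Lpl, 0.59 for Adipoq, 0.13 for Lep, -0.10 for Krt18 and 0.17 for Acta2. Fasn passed without NCD control 4 (0.85) or NCD metformin 4 (0.78), Scd1 without HFD control 4 and Adipoq without NCD control 3 (2.17).

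**Figure D2:**
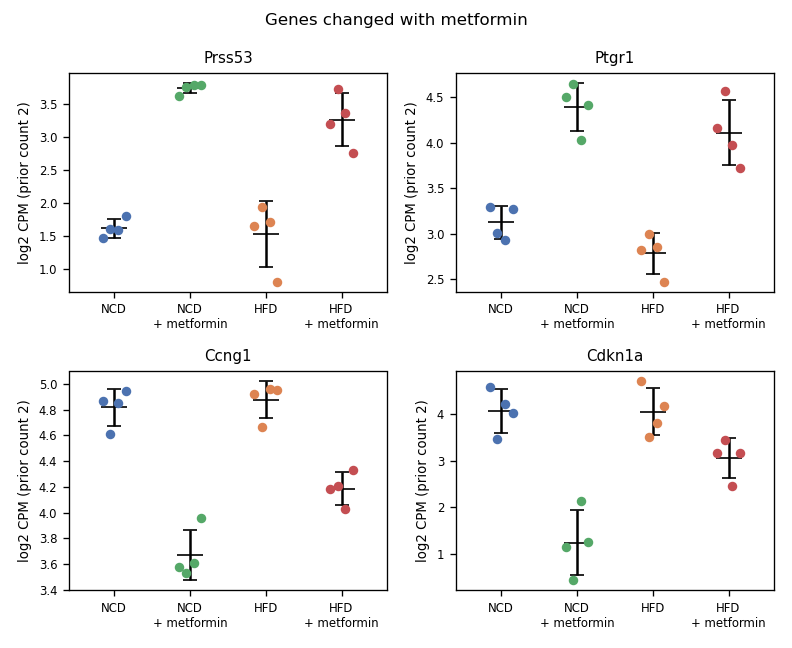
Levels of Prss53, Ptgr1, Ccng1 and Cdkn1a in each library, as log2 CPM with a prior count of 2 on the y axis, by group on the x axis. Points are libraries, horizontal marks and error bars the mean and SD of 4 libraries; Prss53 was 13.3 CPM on NCD and 9.81 CPM on HFD with metformin, against 3.0 and 2.93 CPM without.

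On HFD, metformin raised Prss53 from 2.93 ± 0.885 to 9.81 ± 2.69 CPM, Pycard from 3.76 ± 1.04 to 11.8 ± 2.99 CPM (SD, n = 4). Ptgr1 rose from 6.88 ± 1.02 to 17.6 ± 4.51 CPM and Renbp from 7.91 ± 1.57 to 21.6 ± 5.3 CPM (SD, n = 4). Fibronectin, Fn1, fell from 16.6 ± 4.6 to 5.1 ± 0.773 CPM and Ccng1 from 29.4 ± 2.79 to 18.2 ± 1.59 CPM (SD, n = 4). Further increases were those of Tspan8 (log2 fold change 1.17), the mitochondrial nuclease Endog (1.08), Clybl (0.85), Capg (0.79), Idh2, mitochondrial isocitrate dehydrogenase (0.79), Galk2 (0.72), Bdh1 (0.67), Ndufs7 (0.56) and mt-Co1 (0.52). The channel gene Trpm2 (-1.11), Tgfbr2, a receptor of transforming growth factor beta (-0.83), and Dglucy (-0.68) fell.

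By edgeR's quasi-likelihood test 21 of 12506 genes passed, 16 higher and 5 lower, with 1599 at an unadjusted p under 0.05 against 625 by chance. Adjusted p was 0.00297 for Prss53 (log2 fold change 1.70 ± 0.20 SE), 0.0119 for Pycard (1.60 ± 0.24), 0.00457 for Ptgr1 (1.34 ± 0.18), and 0.00365 for Renbp (1.42 ± 0.18). It was 0.00941 for Fn1 (-1.69 ± 0.24) and 0.0202 for Ccng1 (-0.69 ± 0.12, edgeR), each in the same direction in 4 of 4 libraries. Renbp lies on chromosome X from 73922121 to 73930850 and Fn1 on chromosome 1 from 71585520 to 71653200 (GRCm38). None of the 18 named calls held in every alternative, and 3 held whichever library was left out. Without 1 library the count was 10 (HFD metformin 1), 3 (HFD control 3), 4 (HFD metformin 2), 5 (HFD metformin 3), 44 (HFD metformin 4) or 6 (HFD control 4). Calls were lost in 20 of 30 alternatives for Ndufs7, 19 for Dglucy, 14 for Tgfbr2 and 10 for Ccng1, and in 19 of 29 for Trpm2. In counts rebuilt from TPM 4 genes passed, 4 higher and 0 lower, with Renbp at 0.93 and Dglucy at -0.35, neither called. Without HFD control 3 or HFD metformin 2 the adjusted p of Fn1 was 0.0503 or 0.0529 (edgeR).

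The mitochondrial and ribosomal lists were higher on HFD too, mostly without calls of single genes, with adjusted p = 0.226 with an estimated correlation for the mitochondrial genome and 0.509 for the other 3. Complexes III to V had a median of 0.35 (0 of 33 called, 20 adjusted over the list alone, camera adjusted p = 8.04e-17) and complex I one of 0.31 (1 of 36, 10 adjusted over the list alone, camera adjusted p = 6.01e-14). For cytosolic ribosomal proteins it was 0.31 (0 of 43, 23 adjusted over the list alone, camera adjusted p = 9.43e-18) and for the mitochondrial genome 0.40 (1 of 13, 10 adjusted over the list alone, camera adjusted p = 2.8e-10). Ketone body genes were higher (1 of 7 called, 3 adjusted over the list alone, median 0.41, camera adjusted p = 0.00247, adjusted p = 0.153 with an estimated correlation), with Oxct1 at 0.60 and an adjusted p of 0.0517. Oxct1 passed without HFD metformin 4. Glycolysis (median 0.24, 0 of 17 called, 3 adjusted over the list alone, camera adjusted p = 0.0136, adjusted p = 0.509 with an estimated correlation) was higher. Fatty acid oxidation genes were higher (median 0.21, 0 of 28 called, 0 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.682 with an estimated correlation). So was cell cycle (median 0.88, 0 of 24 called, 0 adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.868 with an estimated correlation). HFD metformin 4 scored 2.03 log2 CPM for it.

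Lower on HFD with metformin were 5 lists, each with adjusted p = 0.509 with an estimated correlation. They were the integrated stress response (median -0.45, 0 of 24 called, 3 adjusted over the list alone, camera adjusted p = 1.31e-06), collagens and extracellular matrix (-0.40, 1 of 25, 6 adjusted over the list alone, camera adjusted p = 2.42e-06), fibroblast markers (-0.42, 0 of 14, 3 adjusted over the list alone, camera adjusted p = 0.00122), macrophage and monocyte markers (-0.27, 0 of 15, 0 adjusted over the list alone, camera adjusted p = 0.03) and involution and STAT3 genes (-0.22, 0 of 27, 0 adjusted over the list alone, camera adjusted p = 0.0458). Among members that did not pass, Mthfd2 had -1.85 and the stress cytokine Gdf15 -2.30, and Mthfd2 passed without HFD metformin 4. Shifted lists numbered 13 of 42. None of the genes named in every comparison passed, with log2 fold changes of 0.15 for Csn2, 0.12 for Wap, 0.18 for Lalba, -0.16 for Fasn, -0.30 for Acaca and 0.13 for Acly. Scd1 had 0.19, with -0.31 for Xdh, -0.17 for Lpl, 0.44 for Adipoq, -0.23 for Lep (0.39 without HFD control 3), 0.24 for Krt18 and 0.22 for Acta2.

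With metformin in both groups, HFD glands again had less Cyp1a1, 2.92 ± 0.762 CPM on NCD against 0.119 ± 0.132 CPM on HFD (SD, n = 4), with 9 counts against 356, a ratio of 3.42% (95% exact counting interval 1.55 to 6.57%). Sqle, squalene epoxidase, fell from 66.9 ± 8.37 to 38.9 ± 3.53 CPM (SD, n = 4). Eda2r was higher, at 2.03 ± 0.844 CPM on HFD and 0.407 ± 0.0725 CPM on NCD, as was Ucp3 at 156 ± 13.5 against 54.9 ± 8.17 CPM (SD, n = 4). Foxo3, a transcription factor held back by insulin signalling, was 21.7 ± 6.81 CPM on HFD and 9.15 ± 2.17 CPM on NCD (SD, n = 4).

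The edgeR quasi-likelihood test called 295 genes, 232 higher and 63 lower on HFD, with 2407 at an unadjusted p under 0.05 against 625 by chance. Adjusted p was 0.0022 for Cyp1a1 (log2 fold change -4.82 ± 0.56 SE) and 0.00406 for Eda2r (2.28 ± 0.29). It was 0.0305 for Sqle (-0.78 ± 0.14), 0.0322 for Ucp3 (1.51 ± 0.28) and 0.0322 for Foxo3 (1.24 ± 0.23, edgeR), in the same direction in 4 of 4 libraries for each. Large increases besides that of Eda2r were those of Adgrf3 (3.96), Tmcc3 (3.04, and 2.01, not called, without HFD metformin 1), Trp53inp1 (2.96), Nr4a2 (2.86), Angptl4 (2.63), Nrip1 (2.46), Cpeb4 (1.99), Sik1 (1.98), Rictor (1.85), Abhd1 (1.84) and Dnase1l2 (1.82). Large decreases besides that of Cyp1a1 were those of Prol1 (-3.26), Rasl11b (-2.60), the mast cell protease Mcpt4 (-2.07), complement C3 (-1.72), Prag1 (-1.5), Gsdma (-1.48), Clca3a2 (-1.45), the zinc transporter Slc39a4 (-1.40), Gsta4 (-1.14) and Vill (-1.13). Of 42 named calls, those of Cyp1a1 and Eda2r ended under no alternative. Those lost in over 15 of 30 included Gsdma (26), Pik3r1 (22), Nr4a2 and Clca3a2 (21), Vill (18), Prag1 and F11r (17), and C3 and Angptl4 (16). Without 1 library the count was 3 (HFD metformin 2), 4 (NCD metformin 2), 5 (HFD metformin 1 or NCD metformin 3), 97 (HFD metformin 4), 107 (HFD control 3), 116 (NCD control 2), 177 (NCD metformin 1) or 181 (HFD control 2). Under library size alone it was 641, 65 higher and 576 lower, and the median of all genes was -0.18. In counts rebuilt from TPM it was 2, 1 higher and 1 lower, and with the length and GC trend removed 150, 102 higher and 48 lower.

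Cholesterol synthesis genes were lower as a list on HFD with metformin, 10 of 24 called lower (17 adjusted over the list alone, median -0.73, camera adjusted p = 6.21e-13, adjusted p = 0.299 with an estimated correlation), including Nsdhl (-1.07) and Lss (-1.04). Of 24 genes of de novo fatty acid synthesis 5 fell (8 adjusted over the list alone, median -0.38, camera adjusted p = 1.27e-06, adjusted p = 0.299 with an estimated correlation), among them Slc25a1 (-0.82). Adipocyte markers were lower as well (median -0.55), with a score of 3.27 ± 0.61 log2 CPM against 3.83 ± 0.5 (SD, n = 4). Antioxidant and NRF2 targets were lower (2 of 17 called, 2 adjusted over the list alone, median -0.26, camera adjusted p = 0.000786, adjusted p = 0.206 with an estimated correlation). Fatty acid oxidation genes were higher, 4 of 28 called (13 adjusted over the list alone, median 0.42, camera adjusted p = 1.33e-05, adjusted p = 0.572 with an estimated correlation), with Cpt1a at 1.15. Insulin and AMPK signalling genes were higher (3 of 22, 4 adjusted over the list alone, median 0.18, camera adjusted p = 0.0344, adjusted p = 0.572 with an estimated correlation), among them Sesn3 (0.82) and Pik3r1 (0.92). The median was -0.01 with library size only. Tight junction genes (2 of 11, 5 adjusted over the list alone, median 0.28, camera adjusted p = 0.0356, adjusted p = 0.339 with an estimated correlation) included Cldn3 (0.65) and F11r (0.43). With library size only the medians of shifted lists moved by -0.19 to -0.15, to 0.25 for fatty acid oxidation, 0.1 for tight junctions and -0.44 for antioxidant genes, and F11r had 0.25, not called.

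Luminal epithelial markers were higher (1 of 15 called, 5 adjusted over the list alone, median 0.25, camera adjusted p = 0.0325, adjusted p = 0.303 with an estimated correlation). So were immediate early genes (1 of 21, 1 adjusted over the list alone, median 0.29, camera adjusted p = 0.013, adjusted p = 0.855 with an estimated correlation), with Dusp1 at 1.72. These 2 medians were 0.08 and 0.13 with library size only. Circadian clock genes were higher (0 of 18, 0 adjusted over the list alone, median 0.53, camera adjusted p = 0.0344, adjusted p = 0.725 with an estimated correlation). Cell cycle genes were higher (0 of 24, 0 adjusted over the list alone, median 1.09, camera adjusted p = 0.0325, adjusted p = 0.855 with an estimated correlation), with HFD metformin 4 at a score of 2.03 log2 CPM. Lower were 4 lists, each with camera adjusted p = 0.0325, and adjusted p = 0.725 with an estimated correlation for glycolysis and 0.855 for the other 3. They were glycolysis (0 of 17, median -0.19), the mitochondrial genome (0 of 13, -0.15), interferon response (0 of 26, -0.20) and adipocyte markers. The last had 1 of 20 called (-0.55), and counts adjusted over the list alone were the same. The first 3 medians were -0.37, -0.32 and -0.37 with library size only. Shifted lists numbered 14 of 42, and 7 without NCD metformin 1, 9 without HFD metformin 1 and 8 without HFD metformin 2. None of the genes named in every comparison passed, with 0.29 for Csn2, 0.31 for Wap, -0.14 for Lalba, -0.42 for Fasn, -0.05 for Acaca and -0.35 for Acly. Scd1 had -0.79, with 0.05 for Xdh, 0.12 for Lpl, -0.56 for Adipoq, 0.79 for Lep, 0.47 for Krt18 and 0.18 for Acta2. Scd1 passed without HFD control 4 (-0.8).

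The interaction asks whether the metformin effect differed between diets. No single gene passed edgeR's quasi-likelihood test, with 1243 genes at an unadjusted p under 0.05, a lowest adjusted p of 0.18 and 22 genes called by DESeq2. The 6 genes with the lowest p-values, which did not pass, were Mgea5, the enzyme that removes O-linked N-acetylglucosamine (1.10 ± 0.18 SE, adjusted p = 0.18), Eda2r (2.23 ± 0.39, adjusted p = 0.18) and Nt5c2 (0.64, adjusted p = 0.293). Nfkbia (1.18), Arhgef15 (-1.43) and Slc25a20 (1.14) followed, all at 0.334 by edgeR. Mgea5 was 58.2 ± 4.97 and 36.7 ± 6.61 CPM without and with metformin on NCD, and 45.9 ± 2.4 and 61.8 ± 8.42 CPM on HFD (SD, n = 4). As lists, each with adjusted p = 0.649 with an estimated correlation, cholesterol synthesis (median -0.55, 0 of 24 called, 7 lower adjusted over the list alone, camera adjusted p = 6.2e-10) and de novo fatty acid synthesis (-0.38, 0 of 24, 0 adjusted over the list alone, camera adjusted p = 6.13e-06) had negative interactions, and fatty acid oxidation a positive one (0.46, 0 of 28, 6 higher adjusted over the list alone, camera adjusted p = 5.22e-07). Members with low p-values were Lss (-1.11), Dhcr7 (-1.27) and Ucp3 (1.51), none past the threshold. Adipocyte markers had -0.16, and -1.25 without NCD control 3.

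In 11 further lists, with no called member, adjusted p with an estimated correlation was 0.763 for adipocyte markers and 0.711 for the other 10. Positive interactions were found for cell cycle (median 1.34, 0 of 24 adjusted over the list alone, camera adjusted p = 0.0151), circadian clock (0.64, 0 of 18, 0.0482), immediate early genes (0.54, 0 of 21, 0.0104) and skeletal muscle markers (8.56, 14 of 16 higher adjusted over the list alone, 0.00156). Negative ones were found for the mitochondrial genome (-0.20, 0 of 13, camera adjusted p = 0.0482), the integrated stress response (-0.21, 0 of 24, 0.0283) and collagens and extracellular matrix (-0.32, 1 of 25 lower adjusted over the list alone, 0.0122). Adipocyte markers (-0.16, 0 of 20, camera adjusted p = 0.0482), endothelial markers (-0.55, 0 of 16, 0.0104), fibroblast markers (-0.24, 0 of 14, 0.0482) and erythroid markers (-1.01, 0 of 5, 0.0472) were negative too. HFD control 1 had an erythroid score of 7.06 log2 CPM. NCD control 3 scored 6.92 log2 CPM for muscle and 4.54 for adipocyte markers, HFD metformin 1 scored 1.98 for muscle, and HFD metformin 4 scored 2.03 for cell cycle. Shifted lists numbered 14 of 42, and 9 without NCD control 1 or NCD metformin 1, 8 without NCD control 4 and 7 without HFD metformin 4. Without NCD control 4, 1 gene passed edgeR's test, Ucp3 (1.78). Interaction values of the genes named in every comparison were 0.08 for Csn2, 0.02 for Wap, -0.13 for Lalba, -0.79 for Fasn, -0.54 for Acaca and -0.49 for Acly. Scd1 had -0.31, with -0.45 for Xdh, -0.12 for Lpl, -0.15 for Adipoq (-1.74 without NCD control 3), -0.36 for Lep (0.26 without HFD control 3), 0.34 for Krt18 and 0.05 for Acta2, with none past the threshold.

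Averaged over treatments, HFD lowered Cyp1a1 by edgeR's quasi-likelihood test (log2 fold change -5.28 ± 0.44 SE, adjusted p = 1.67e-05) and Prol1 (-4.15 ± 0.49, adjusted p = 0.000997). Also lower were complement C3 (-1.51), the acute phase protein Orm1 (-1.57) and the chitinase-like Chil1 (-1.24, in 7 of 8 libraries), with Rasl11b (-2.18), Slc39a4 (-1.5), the aldose reductase-like Akr1b8 (-1.39), Gsta3 (-1.38), Gsdma (-1.33) and Vill (-1.19, and -0.67, not called, in counts rebuilt from TPM). Serpina11 rose from 1.9 ± 0.599 to 6.48 ± 1.19 CPM without metformin and from 2.53 ± 0.788 to 6.58 ± 2.8 CPM with it (SD, n = 4; log2 fold change 1.58 ± 0.22, edgeR adjusted p = 0.0046). Ddah1 (1.58) rose as well, as did Cilp (1.66), Adcy2 (1.5), Limch1 (1.19), Klf11 (1.17), Eda2r (1.17, and 0.06 without metformin), Vcan (1.13), Klf10 (1.04), Fam189a2 (1.01), Itgav (1.01) and Derl3 (0.90).

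The test called 117 genes, 65 higher and 52 lower, with 2174 at an unadjusted p under 0.05 against 625 by chance. Of 35 named calls 9 held in every alternative, Cyp1a1 and Prol1 among them, and 16 whichever library was left out. Without 1 library the count of genes was 28 (HFD control 3), 30 (NCD metformin 3), 50 (NCD control 2), 52 (HFD control 4), 57 (HFD metformin 2), 58 (NCD metformin 1), 59 (NCD control 4), 62 (NCD metformin 2), 69 (HFD metformin 1) or 180 (NCD metformin 4). The count was 111 with DESeq2 size factors, 54 higher and 57 lower. It was 106 with TMM without milk protein genes, 51 higher and 55 lower. In counts rebuilt from TPM it was 35, 13 higher and 22 lower, so that the majority turned in these alternatives. Under library size alone it was 1595, 49 higher and 1546 lower, and the median of all genes was -0.17. Calls lost in over 14 of 29 alternatives included those of Cilp (22), Cpt1a (20), Gclm (19), Me1 and Mfge8 (18), Vcan (17), Orm1 and Gsta3 (16) and Limch1 (15).

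Antioxidant and NRF2 targets were lower averaged over treatments, with 3 of 17 called lower and 9 adjusted over the list alone (median -0.29, camera adjusted p = 5.84e-07, adjusted p = 0.0175 with an estimated correlation), among them Gsta4 (-1.04) and Gclm (-0.29, and -0.09 with metformin). Cholesterol synthesis was lower (3 of 24 called, 15 lower and 1 higher adjusted over the list alone, median -0.41, and -0.09 without metformin, camera adjusted p = 3.51e-09, adjusted p = 0.494 with an estimated correlation). De novo fatty acid synthesis was lower (3 of 24, 7 adjusted over the list alone, median -0.17, and 0.07 without metformin, camera adjusted p = 0.00132, adjusted p = 0.494 with an estimated correlation), with Me1 at -0.34. Milk proteins were higher (2 of 17, 9 adjusted over the list alone, median 0.19, camera adjusted p = 0.00633, adjusted p = 0.494 with an estimated correlation), with Glycam1 at 0.84 in 7 of 8 libraries. Milk fat globule and secretion genes were higher (1 of 13, 4 adjusted over the list alone, median 0.19, camera adjusted p = 0.0274, adjusted p = 0.538 with an estimated correlation), with Mfge8 at 0.39. With library size only the medians of all shifted lists moved by -0.18 to -0.16, as that of all genes did, so that smaller medians turned sign by construction, which says nothing about these lists. Medians were then -0.46 for antioxidant genes, -0.33 for fatty acid synthesis and 0.02 for milk proteins and for milk fat globule genes, and Mfge8 had 0.23, not called. Also higher were fatty acid oxidation (1 of 28, 3 adjusted over the list alone, median 0.11, -0.10 without metformin, and -0.07 with library size only, camera adjusted p = 0.0215, adjusted p = 0.692 with an estimated correlation), with Cpt1a at 0.75. Insulin and AMPK signalling was higher (1 of 22, 3 adjusted over the list alone, 0.12, and -0.04 with library size only, camera adjusted p = 0.0451, adjusted p = 0.538 with an estimated correlation). So were tight junctions (1 of 11, 4 adjusted over the list alone, 0.09, and -0.08 with library size only, camera adjusted p = 0.0351, adjusted p = 0.494 with an estimated correlation).

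The integrated stress response was higher (1 of 24, 3 adjusted over the list alone, median 0.33, 0.07 with metformin, and 0.16 with library size only, camera adjusted p = 0.00461, adjusted p = 0.692 with an estimated correlation). Glycolysis was lower (1 of 17, 1 adjusted over the list alone, median -0.15, camera adjusted p = 0.00799, adjusted p = 0.538 with an estimated correlation). So were complex I (0 of 36, -0.09, camera adjusted p = 0.0295) and complexes III to V (0 of 33, -0.07, camera adjusted p = 0.0351). Both had 0 adjusted over the list alone and adjusted p = 0.786 with an estimated correlation. With library size only these 3 medians were -0.32, -0.26 and -0.24. Muscle markers were lower (0 of 16, 0 adjusted over the list alone, -2.42, and 1.73 with metformin, camera adjusted p = 0.0274, adjusted p = 0.786 with an estimated correlation), with NCD control 3 at a muscle score of 6.92 log2 CPM. Shifted lists numbered 13 of 42, and 8 without NCD metformin 2. None of the genes named in every comparison passed, with 0.25 for Csn2, 0.31 for Wap, -0.08 for Lalba, -0.03 for Fasn, 0.22 for Acaca and -0.10 for Acly. Scd1 had -0.63, with 0.28 for Xdh, 0.18 for Lpl, -0.48 for Adipoq, 0.97 for Lep, 0.30 for Krt18 and 0.15 for Acta2, and a lowest adjusted p of 0.0613 for Scd1 (edgeR). Scd1 passed without HFD control 4 (-0.8) and Csn2 without HFD metformin 4 (0.29), and Adipoq had 0.3 without NCD control 3.

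Averaged over diets, metformin raised Prss53 (log2 fold change 1.92 ± 0.14 SE, edgeR adjusted p = 2.82e-06), mt-Co1 (0.65 ± 0.06, adjusted p = 4.07e-05), Ptgr1 (1.31 ± 0.12, adjusted p = 4.07e-05) and Pycard (1.53 ± 0.17, adjusted p = 0.00016). It lowered Cdkn1a (-1.91 ± 0.24, edgeR adjusted p = 0.000499), Gdf15 (-3.00 ± 0.42, adjusted p = 0.000936) and Pip, prolactin-induced protein (-3.80 ± 0.59, adjusted p = 0.00182). Increases were also found for the immunoglobulin genes Ighv4-1 (2.88) and Iglc3 (1.81), in 7 of 8 libraries each, which belong to a multigene family. Others were Pcolce2 (1.43), Rragd (1.36), Glrb (1.3), Angptl2, Bcl2l14 (1.14), Endog (1.09), the sterol 27-hydroxylase Cyp27a1 (1.07) and Galk2 (0.69). Further decreases were those of Myh1 (-5.92), Cyp24a1 (-3.98), Prol1 (-2.42), carbonic anhydrase Car6 (-2.40), Zfp469 (-2.06), Adgrf3 (-1.95, and -0.20 on HFD), Gstp2 (-1.86, and 0.26 on HFD), Gsta3 (-1.73) and Psrc1 (-1.64). Cyp24a1, Prol1 and Gstp2 were lower in 7 of 8 libraries and Adgrf3 in 6 of 8. Myh1 was 123 CPM in NCD control 3.

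The edgeR quasi-likelihood test called 1424 genes, 728 higher and 696 lower, with 3612 at an unadjusted p under 0.05 against 625 by chance. Of 40 named calls 31 held in every alternative, Prss53, Ptgr1, Pycard, mt-Co1, Cdkn1a, Gdf15 and Pip among them. Without 1 library the count of genes was 837 (NCD control 1), 711 (NCD metformin 2), 824 (HFD control 3), 812 (HFD metformin 2), 793 (HFD metformin 3) or 795 (HFD control 4). Under library size alone it was 1254, 357 higher and 897 lower, and in counts rebuilt from TPM 880, 549 higher and 331 lower. The call of Gstp2 was lost in 16 of 29 alternatives.

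The mitochondrial and ribosomal lists rose with metformin averaged over diets, with adjusted p = 0.165 with an estimated correlation for the mitochondrial genome and 0.477 for the other 3. Of 33 nuclear genes of complexes III to V 21 rose (30 adjusted over the list alone, median 0.38, camera adjusted p = 1.83e-16). Of 36 in complex I 17 rose (26 adjusted over the list alone, median 0.34, camera adjusted p = 6.95e-14). Of 43 cytosolic ribosomal protein genes 23 rose (34 adjusted over the list alone, median 0.28, camera adjusted p = 1.26e-15), and of 13 mitochondrial genome genes 11 rose (12 adjusted over the list alone, median 0.44, camera adjusted p = 3.24e-12). None of their members fell. With the length and GC trend removed the medians of complexes III to V and of ribosomal proteins were 0.22 and 0.139. Cyc1, cytochrome c1, rose by 0.51 and Rpl3 by 0.41 on the log2 scale. Fold changes fell with coding length across 10447 genes, which are not independent replicates (Spearman's rho = -0.357), with medians of 0.16 in the shortest sixth of the genes and -0.14 in the longest sixth. Of 7 ketone body genes 3 rose (3 adjusted over the list alone, median 0.32, camera adjusted p = 0.00833, adjusted p = 0.165 with an estimated correlation), with Bdh1 at 0.70 and Oxct1 at 0.67. Glycolysis was higher (6 of 17, 6 adjusted over the list alone, median 0.14, camera adjusted p = 0.00661), as was lactose synthesis and glucose uptake (3 of 14, 3 adjusted over the list alone, 0.14, camera adjusted p = 0.032). Adjusted p was 0.477 with an estimated correlation for both, and their medians were 0.07 and 0.08 with library size only.

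**Figure D3:**
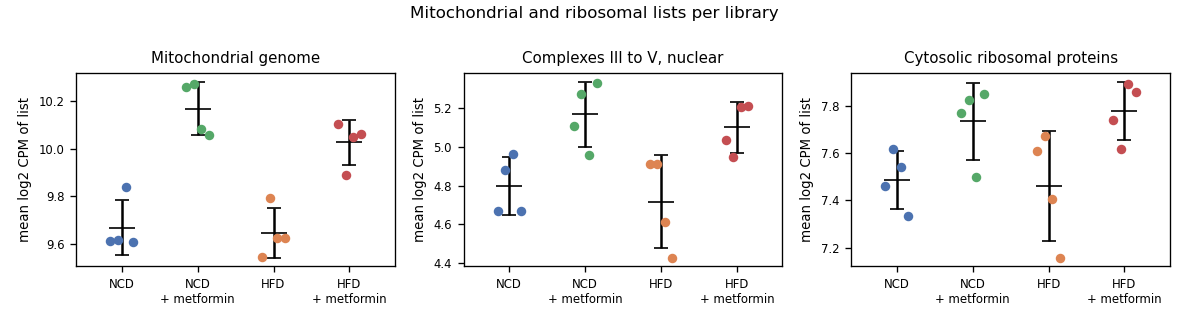
Scores of the mitochondrial genome, of nuclear subunits of complexes III to V and of cytosolic ribosomal proteins in each library, as the mean log2 CPM of the list on the y axis, by group on the x axis. Points are libraries, horizontal marks and error bars the mean and SD of 4 libraries; averaged over diets the list medians of log2 fold changes were 0.44, 0.38 and 0.28.

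De novo fatty acid synthesis was higher averaged over diets (4 of 24, 4 adjusted over the list alone, median 0.16, and -0.01 on HFD, camera adjusted p = 0.0144, adjusted p = 0.612 with an estimated correlation). Cholesterol synthesis was higher (2 of 24, 5 adjusted over the list alone, 0.17, and -0.09 on HFD, camera adjusted p = 0.00905, adjusted p = 0.614 with an estimated correlation), and adipocyte markers too (0 of 20, 0 adjusted over the list alone, 0.31, camera adjusted p = 0.0217, adjusted p = 0.685 with an estimated correlation). With library size only the first 2 medians were 0.08 and 0.1, and without NCD control 3 that of adipocyte markers was 0.82. Lower were 4 lists, each with adjusted p = 0.614 with an estimated correlation. They were immediate early genes (2 of 21, 2 adjusted over the list alone, median -0.68, camera adjusted p = 8.16e-05), the integrated stress response (5 of 24, 5 adjusted over the list alone, -0.29, camera adjusted p = 0.00231), collagens and extracellular matrix (6 of 25, 7 adjusted over the list alone, -0.29, camera adjusted p = 0.00261), with Fn1 at -0.90 (-0.11 on NCD), and fibroblast markers (4 of 14, 4 adjusted over the list alone, -0.33, camera adjusted p = 0.0427). Involution and STAT3 genes were lower (6 of 27, 7 adjusted over the list alone, -0.30, camera adjusted p = 0.00144), as were macrophage and monocyte markers (1 of 15, 6 adjusted over the list alone, -0.25, camera adjusted p = 0.00848). Adjusted p was 0.477 with an estimated correlation for both. Muscle markers were lower (2 of 16, 2 adjusted over the list alone, -2.46, and 1.53 on HFD, camera adjusted p = 0.0267, adjusted p = 0.761 with an estimated correlation), with NCD control 3 at a muscle score of 6.92 log2 CPM. Shifted lists numbered 17 of 42. Of the genes named in every comparison Acly passed (0.37 ± 0.10 SE, edgeR adjusted p = 0.0328, 0.13 on HFD in 3 of 4 libraries). Its call was lost in 13 of 29 alternatives (highest adjusted p = 0.084, edgeR). The others had 0.12 for Csn2, 0.11 for Wap, 0.25 for Lalba, 0.23 for Fasn, and -0.03 for Acaca. Scd1 had 0.35, with -0.09 for Xdh, -0.11 for Lpl, 0.51 for Adipoq, -0.05 for Lep (0.26 without HFD control 3), 0.07 for Krt18 and 0.20 for Acta2. Adipoq passed without NCD control 3 (1.3), Scd1 without HFD control 4 (0.5) and Lalba without HFD metformin 4 (0.3).

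The other lists were shifted in no contrast. Their lowest camera adjusted p was 0.331 for triglyceride synthesis, 0.0651 for fatty acid uptake and transport, 0.738 for gluconeogenesis, 0.384 for metformin transporters, 0.0724 for the unfolded protein response and ER chaperones, 0.682 for prolactin and STAT5 signalling and 0.0553 for calcium and serotonin in lactation. It was 0.227 for inflammatory cytokines and chemokines, 0.239 for brown or beige adipocyte genes, 0.175 for myoepithelial markers, 0.222 for B cell and lymph node markers, 0.072 for plasma cell markers and 0.206 for Schwann cell and nerve markers. Median, mean and test differed in sign in 3 to 9 of 42 lists per comparison, and in 0 of the shifted ones.

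Across the 12506 genes, which are not independent replicates, log2 fold changes of the diet effect without and with metformin had a Pearson correlation of 0.088, and 12 of 40 random relabellings gave one as large. Of 298 genes called in either, 211 had the same sign (70.8%, against 56.6% of all genes), and both comparisons called 1 gene higher, Scnn1b, and 4 lower, Cyp1a1, Prol1 and Adig among them, against 0.04 and 0.03 for independent lists. The correlation was -0.032 over genes of at least 10 CPM (19 of 40 relabellings as large) and -0.032 without NCD metformin 2. The metformin effects on NCD and HFD had a correlation of 0.181, and 7 of 40 relabellings gave one as large, and of 0.096 over genes of at least 10 CPM (22 of 40 as large). Of 1260 genes called in either, 1037 had the same sign (82.3%, against 64.9% of all genes), with 13 called higher and 3 lower in both, against 0.64 and 0.3 for independent lists. The metformin effect on HFD and the diet effect without metformin share the HFD control libraries. Their correlation was -0.408, against -0.515 simulated with no effect, and their covariance -0.0846 against -0.0641 simulated, a difference of -0.0205. With the shared libraries split between the comparisons the correlation averaged -0.141 over 6 splits, from -0.245 to -0.045.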

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

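The tests of the mitochondrial and ribosomal pattern and of the muscle pattern were chosen after the results were seen, as were the p53 list and the removal of the length and GC trend, while the splits of the libraries were fixed before the data were examined. Within groups of 4 a library stood apart where its gap to the nearest other, relative to the range of the group, exceeded Dixon's 95% critical value. Chance gives this in about 1 of 20 groups, and it was met in 58 of 888 against 44.4 by chance.

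Among list scores (log2 CPM), HFD control 4 stood apart for milk proteins (12.12), metformin transporters (1.73) and immediate early genes (4.21), and HFD control 1 for cholesterol synthesis (3.62) and erythroid markers (7.06). NCD control 3 did for gluconeogenesis (5.42) and the mitochondrial genome (9.84), and NCD control 4 for fatty acid uptake (6.21). NCD metformin 2 did for gluconeogenesis (5.12), library 3 for prolactin and STAT5 signalling (2.86) and library 4 for plasma cell markers (2.27). HFD metformin 3 did for milk fat globule genes (8.62) and Schwann cell markers (1.25). For skeletal muscle markers the libraries apart were NCD metformin 2 (0.23), HFD control 3 (0.39) and HFD metformin 1 (1.98).

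Among named genes (log2 CPM), HFD metformin library 1 stood apart for Prol1 (1.97), Cyc1 (6.33) and the muscle genes Acta1 (3.96), Tcap (0.38), Tnnc2 (1.05), Tnnt3 (3.56), Ryr1 (2.13) and Mylpf (1.54). HFD metformin library 2 did for Csn3 (15.05), library 3 for Gsdma (-1.38) and library 4 for Fdps (5.65). NCD metformin library 1 did for Adipoq (4.16), library 2 for Kcnk5 (7.63), Ckm (1.49), Cox6a1 (6.74), Tnnc2 (-1.19) and Iglc3 (-0.89), and library 3 for Myh1 (-2.02) and Prag1 (4.95). NCD control library 1 did for Eno1 (7.42), library 2 for Cilp (1.47), and library 3 for Gstm1 (3.42), Adipoq (6.24), Ly6a (3.58) and Sesn3 (2.74). NCD control library 4 did for Kdr (4.36), Tspan8 (3.07), Slc39a4 (2.81), Car6 (-0.65), Adcy2 (-0.95) and Klf10 (1.05). HFD control library 1 did for Cpt1a (2.23) and Sesn3 (1.83), and library 2 for Lgals12 (2.76), Ccng1 (4.66), Tmcc3 (4.12), Mgea5 (5.63) and Nfkbia (6.02). HFD control library 3 did for Myh1 (0.61), and library 4 for Scd1 (8.47), Eno1 (7.46) and Itgav (4.63).

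The metformin effect differed between diets for 14 lists by camera on the interaction at a preset correlation, and for none with an estimated one. Adjusted p was 6.13e-06 for de novo fatty acid synthesis, 6.2e-10 for cholesterol synthesis, 5.22e-07 for fatty acid oxidation, 0.0283 for the integrated stress response, 0.0151 for cell cycle, 0.0122 for collagens and 0.00156 for skeletal muscle markers. It was 0.0104 for immediate early genes and for endothelial markers, 0.0472 for erythroid markers, and 0.0482 for the mitochondrial genome, circadian clock, adipocyte and fibroblast markers.

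Mitochondrial and ribosomal transcripts were higher with metformin averaged over diets (camera, with adjusted p = 0.165 with an estimated correlation for the mitochondrial genome and 0.477 for the other lists). The share of counts left by milk transcripts changed by 0.017 ± 0.034 (log2, SE), which argues against milk transcripts taking counts as the whole cause. Removing the trend with coding length and GC content left the mitochondrial genome at 0.469 (0.443 before), which argues against that trend there. For complexes III to V the median went from 0.381 to 0.22 (15 genes called, 21 before; mean 0.376 ± 0.088 before and 0.206 ± 0.048 after, SE) and for ribosomal proteins from 0.284 to 0.139 (6 called, 23 before; mean 0.281 ± 0.083 and 0.137 ± 0.053), the calls ending as the fold changes shrank. The trend and metformin cannot be told apart for these lists, since their genes are short (median coding length 339 and 567 bases), and an effect of metformin stays open.

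A list of p53 targets, written after Cdkn1a and other members had been seen lower with metformin on NCD, had 21 of 35 members called lower, with a median of -0.806. It was -0.881 with the length and GC trend removed and -0.634 with the immediate early score of each library as a covariate. These values include members that prompted the list, so they do not test it. The 22 members not seen before had a median of -0.406, with 8 called lower and 18 negative (camera adjusted p = 8.38e-05 over the 12 tests of this list, and adjusted p = 0.0116 with an estimated correlation). These 22 had a median of -0.133 on HFD and of 0.369 in the interaction (camera adjusted p = 0.00142, and adjusted p = 0.0312 with an estimated correlation). Lower expression of p53 targets with metformin on NCD may be a candidate explanation, as a hypothesis found on the same data, and differences in cell makeup were not tested.

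Skeletal muscle transcripts were lower with metformin on NCD. Of 12 called markers 1 was called without NCD control library 3, in which Acta1, Ckm and Myh4 reached 414, 448 and 1721 CPM, and in 2 all control libraries lay above all metformin libraries. This argues against lower expression in every library and is consistent with muscle tissue in that library.

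Other splits of the libraries, uncorrected over tests, asked if chance labels give such counts, but not if chance between animals does. For gene counts no other split was as large without metformin (8 genes, highest other 1, 1 of 35 splits, the lowest share possible). The same held for metformin on NCD (1255, other 31, 1 of 35) and on HFD (21, other 1, 1 of 35). It held for diet with metformin (295, other 1, 1 of 35). The same held averaged over treatments (117, other 22, 1 of 100) and over diets (1424, other 32, 1 of 99). For the interaction edgeR called 0 genes (highest other 68, source not tested, 99 of 99), so the splits decide nothing on chance. There 1243 genes had an unadjusted p under 0.05, DESeq2 called 22 and limma-voom 0. For counts of lists chance cannot be excluded in any contrast. Counts were 6 without metformin (other 16, 33 of 35) and 15 for metformin on NCD (18, 5 of 35). They were 13 for metformin on HFD (15, 5 of 35) and 14 for diet with metformin (18, 3 of 35). The interaction had 14 (18, 13 of 99). The average over treatments had 13 (19, 17 of 100) and that over diets 17 (20, 3 of 99).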

How the results depend on the processing

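Of the alternatives, only removal of the length and GC trend and the 3 exclusions of a pair of libraries were chosen after the results were seen. Of 210 called values of named genes, 71 kept their call in every alternative, 139 lost it in at least 1, and 1 changed direction; the cause was not tested. No paired analysis was possible because no label pairs libraries across groups. DESeq2, which gave 9.9 to 13.9% false calls on simulated counts, called more genes than edgeR in each of the 7 comparisons. Depth limits HFD control 4 and HFD metformin 1 most.

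Counts of genes are given in the order of diet without metformin, metformin on NCD, metformin on HFD, diet with metformin, interaction, diet average and metformin average. Leaving out each library gave 2 to 13, 180 to 1461, 3 to 44, 3 to 384, 0 to 1, 28 to 180 and 711 to 1505. Counts that moved over 1.5 times were, with library size only, 39 for diet without metformin, 7 for metformin on HFD, 641 for diet with metformin and 1595 for the diet average. With counts rebuilt from TPM they were 619 for metformin on NCD, 4 for metformin on HFD, 2 for diet with metformin, 35 for the diet average and 880 for the metformin average. The title number term gave 5 for diet without metformin, and only the 2 groups compared 1 for metformin on HFD and 91 for diet with metformin. Without the 2 libraries highest in muscle markers they were 5, 10, 5 and 53 for diet without metformin, metformin on HFD, diet with metformin and the diet average. Without the 2 libraries with the fewest counts they were 1, 10 and 30 for metformin on HFD, diet with metformin and the diet average. Without the libraries highest in cell cycle and muscle they were 781, 109 and 73 for metformin on NCD, diet with metformin and the diet average. With the trend removed diet with metformin had 150. DESeq2 gave 65, 170, 769, 22 and 468 for diet without metformin, metformin on HFD, diet with metformin, the interaction and the diet average.

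Counts of lists were 14 with library size only and 11 with the title number term for diet without metformin, and 9 and 6 without the libraries with the fewest counts for diet with metformin and the interaction. In the order above, an estimated correlation gave 1, 0, 0, 0, 0, 1 and 0 and fry 1, 7, 2, 5, 0, 2 and 10. Leaving out each library gave 6 to 13 for diet without metformin, 7 to 15 for diet with metformin, 7 to 15 for the interaction and 8 to 16 for the diet average. The correlation of the diet effect between treatments was -0.032 over genes of at least 10 CPM and from -0.032 to 0.263 when each library was left out.

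Of the named values that turned direction only that of Ryr1 was called. For diet without metformin, Adipoq had 1.17 and 1.16 without the muscle or the cell cycle and muscle libraries, 0.22 with voom, and -0.75 to 1.16 when each library was left out. Acta2 had -0.03 with library size only and -0.16 to 0.3, Lalba 0.07 without the fewest counts, 0.01 with the trend removed and -0.1 to 0.07, Acly -0.01 and Krt18 -0.04 with library size only. For metformin on NCD, Ryr1, which was called, had 0.07 and 0.05 without the muscle or the cell cycle and muscle libraries and -7.84 to 0.05 when each library was left out. Lep had -0.07 with the title term, -0.05 with the trend removed and -0.16 to 0.39, Lpl 0.05 with the trend removed and -0.12 to 0.01, Wap -0.09 with the trend removed and Xdh -0.04 to 0.23. For metformin on HFD, Acta2 had 0 without the cell cycle and muscle libraries, Wap 0 without the fewest counts and -0.04 with the trend removed, and Lep -0.5 to 0.39. For diet with metformin, Acaca had 0.02 from TPM, 0.01 without the muscle libraries, 0.01 without the fewest counts and -0.21 to 0.09, Acta2 -0.05 without the cell cycle and muscle libraries and -0.04 to 0.32. Lpl had -0.04 with library size only, -0.06 without the cell cycle and muscle libraries and -0.05 to 0.22, and Xdh -0.11 with library size only, -0.05 with the trend removed and -0.05 to 0.22. For the interaction, Acta2 had -0.24 without the cell cycle and muscle libraries and -0.17 to 0.33, Wap 0 with library size only, 0 with the title term, -0.11 without the fewest counts and -0.1 to 0.11. Lpl had 0.02 without the fewest counts, Adipoq -1.74 to 0.18, Csn2 0 to 0.15 and Lep -0.63 to 0.26. For the diet average, Adipoq had 0.16 and 0.39 without the muscle or the cell cycle and muscle libraries and -0.66 to 0.3, Fasn 0.01 with voom and -0.11 to 0.08, and Acta2 0 with library size only. For the metformin average, Acaca had 0.02 without the fewest counts, 0.18 with the trend removed and -0.11 to 0.06, Xdh 0.05 from TPM and 0.03 with the trend removed, and Wap -0.07 with the trend removed. Lep had 0.04 with voom and -0.2 to 0.26, and Krt18 0 to 0.12.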

Other observations

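The test of the aryl hydrocarbon receptor list was written before the values of its remaining members were seen, but after Cyp1a1 had been seen lower on HFD, and the spread used to decide it was chosen after its result. The hypothesis was that targets of the receptor other than Cyp1a1 were lower on HFD averaged over treatments, and a median of 0 or higher had been set as the value against it. Of 9 members not yet seen 3 were expressed enough to test. Nfe2l2 had 0.37 ± 0.11 (SE), Tiparp 0.35 ± 0.35 and Ugt1a7c -0.12 ± 0.23 (lowest adjusted p = 0.1, edgeR), with a median of 0.353, above 0 by more than the SD between them, 0.278. With Nqo1 (-0.07 ± 0.24) and Xdh (0.28 ± 0.10), whose lists had been read before, the median was 0.277 and the SD 0.239. This argues against a fall shared by the tested targets, though by a small margin and over few genes. Targets that were not expressed enough to test stay open.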
